A study of Mus musculus with 30 samples.

How the data were processed

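Gene expression was measured with single-channel Affymetrix arrays carrying 45101 probe sets in mouse FZ and GP cells from long bones of 18.5 dpc embryos. The 30 arrays formed 10 groups of 3, taken from the sample titles: each cell type untransduced at 0 h, and at 8 h and 48 h after transduction with the empty pMY retroviral vector or with the vector carrying EWS-FLI1. RNA was isolated with a QIAGEN kit, per the labels. The deposited values were array intensities on a linear scale, 1 column per array, and were produced with MAS5, per the submitters' processing notes. The MAS5 version, the scaling target and any later transformation are not given in the sources used here.

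The deposited intensity columns were not on 1 scale. The column medians were 12.7 to 16.3 in the 6 empty-virus arrays of 48 h, 3.19 to 5.40 in the 6 EWS-FLI1 arrays of 48 h and 0.484 to 1.64 in the 18 arrays of 0 h and 8 h, a 33.7-fold range. From the values, the 6 empty-virus columns of 48 h held plain signals with 1 decimal, and each of the other 24 columns was described by a factor and a power, between 0.868 and 1.10, of such signals. This is inferred from the values, and the reason for the rescaling stays unknown. Quantile normalization of the deposited values, which removes both, was therefore applied by a rule set before the data were examined, which asked for it where array medians differed by over 2 times. An offset of 1.21, the 25th percentile of all normalized values, was added before log2 was taken, so log2 fold changes understate the change of dim genes. Probe sets above 4.43, the median of all normalized values, on at least 3 of the 30 arrays were kept. After 64 control probe sets were left out, 30448 probe sets remained. In the platform annotation 34958 probe sets had 1 gene symbol, 932 had several and 9160 had none. Genes were named only from probe sets with 1 symbol, and 0 symbols needed an update through the gene identifier. The probe set with the highest mean log2 signal represented each gene, which gave 13985 genes. All value columns of the table were assigned to a sample.

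Differential expression was tested with limma 3.58.1 in R 4.3.3. A linear model with 1 mean per group was fitted to all 30 arrays, leaving 20 residual degrees of freedom, with empirical Bayes moderation and an intensity trend. P values were adjusted by Benjamini-Hochberg within each of the 17 comparisons, and a gene was called at an adjusted p below 0.05. Every adjusted p of a gene below comes from limma. Differences between EWS-FLI1 effects were tested as interaction contrasts in the same model. Gene lists were tested with camera, from limma, with a preset inter-gene correlation of 0.01 and again with an estimated correlation, adjusted over the lists. The 33 lists, fixed before the data were examined, held 558 distinct genes, of which 493 were measured, 27 were too dim and 38 had no probe set of a single gene. They covered EWS-FLI1-induced and EWS-FLI1-repressed targets known from Ewing sarcoma, ETS family and fusion partners, neural, articular, growth plate cartilage, hypertrophic, osteoblast, tendon and fibroblast, muscle, endothelial, macrophage and leukocyte, erythroid, osteoclast, adipocyte, Schwann, keratinocyte, cell cycle, interferon, inflammatory, p53, Wnt, Hedgehog, IGF axis, TGF-beta and BMP, matrix protease and crosslinking enzyme, posterior Hox, immediate early, ERK feedback, unfolded protein and amino acid stress, glycolysis and hypoxia, cholesterol synthesis, and actin cytoskeleton and contractile genes.

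Genes were named by a rule set before the data were examined. For FZ against GP at 0 h, the EWS-FLI1 effects and the differences of these effects between cell types, the rule took up to 6 called genes with the largest increase and up to 6 with the largest decrease, with nonoverlapping values of the groups where 2 groups were compared. It added up to 4 called members with the smallest p from each list that passed its test or had at least 3 called members. Fli1, Ewsr1, Erg and members of the EWS-FLI1 target, articular and growth plate lists could be named whatever their result. For the other comparisons it took up to 3 genes each way and up to 2 per list. Genes named outside the rule are said to have been chosen after their values were seen. For a gene of the largest changes between 2 groups, all 3 arrays of 1 group lay above all 3 of the other. Such separation is found by chance in 10% of genes.

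Nothing in the labels says that the 3 arrays of a group came from separate animals or cultures, so p values measure only the spread between these samples. In each of the 8 transduced groups some arrays were high in Xist and low in the Y-linked Eif2s3y and others the reverse, so the 3 arrays were not all repeats of 1 sample. At 0 h, and between arrays alike in Xist, the spread may be technical. The number of arrays limits the precision. The calculation was tested on simulated data with known changes in 13985 genes. At a log2 change of 1, the share of changed genes called was 38.8% for FZ against GP at 0 h, 40.3% for EWS-FLI1 in FZ cells at 48 h, 41.8% in GP cells at 48 h and 19.4% for the difference between these effects. At a log2 change of 2 the shares were 75.8%, 74.2%, 71.2% and 42.4%. Unchanged genes made up 7 of 95, 6 of 89, 6 of 88 and 3 of 45 calls. The simulated noise was independent between genes and had, for each gene, the same SD on every array. Real arrays differed in spread, with array quality weights of 0.0825 to 3.83, so the shares in the real data may differ. The alternatives were other offsets, a floor, quantile normalization of log2 values, equal array medians, no filter and a stricter filter at the 75th percentile, all probe sets, the mean of a gene's probe sets, only the groups of a comparison, no trend, array quality weights, the replicate number as a block, each array left out in turn and a 2-fold minimum. Signals recovered from the inferred factor and power, terms for the 3'/5' actin ratio, for Xist and for the replicate number within each virus, and fits without GP arrays of 8 h were added after the data were seen. Signal recovery and figures used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.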

Results

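Transcript levels were profiled in 2 kinds of osteochondrogenic cell dissected from the long bones of mouse embryos at 18.5 dpc, with and without EWS-FLI1, the fusion transcription factor that drives Ewing sarcoma. FZ is used here as the sample titles give it, and GP, which the labels spell growth place, is read as growth plate. The labels spell out FZ as facial zone, whereas the series text writes eSZ in its place, and which name describes these cells is not settled here. Each cell type was profiled untransduced at 0 h and, at 8 h and 48 h, with the empty retroviral vector or the vector carrying EWS-FLI1, on 3 arrays per group and 30 arrays in all. The series asks how the cell context bears on the response to EWS-FLI1. After filtering, 13985 genes were compared, and values below are log2 signals or log2 differences with the standard error (SE) of the model, n = 3 per group.

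RNA integrity differed between groups. The actin 3'/5' signal ratio, which rises when RNA is degraded, was 3.13 to 14.3 on the 6 GP arrays of 8 h and 1.46 to 3.03 on the other 24. Its mean was 9.23 in the 3 GP empty-virus arrays of 8 h and 5.36 in the 3 GP EWS-FLI1 arrays of 8 h. The mean rank correlation of an array with its own group was 0.686 to 0.763 for these 6 arrays and 0.869 to 0.942 for the others. Their array quality weights in limma were 0.0825 to 0.395.

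**Figure D1:**
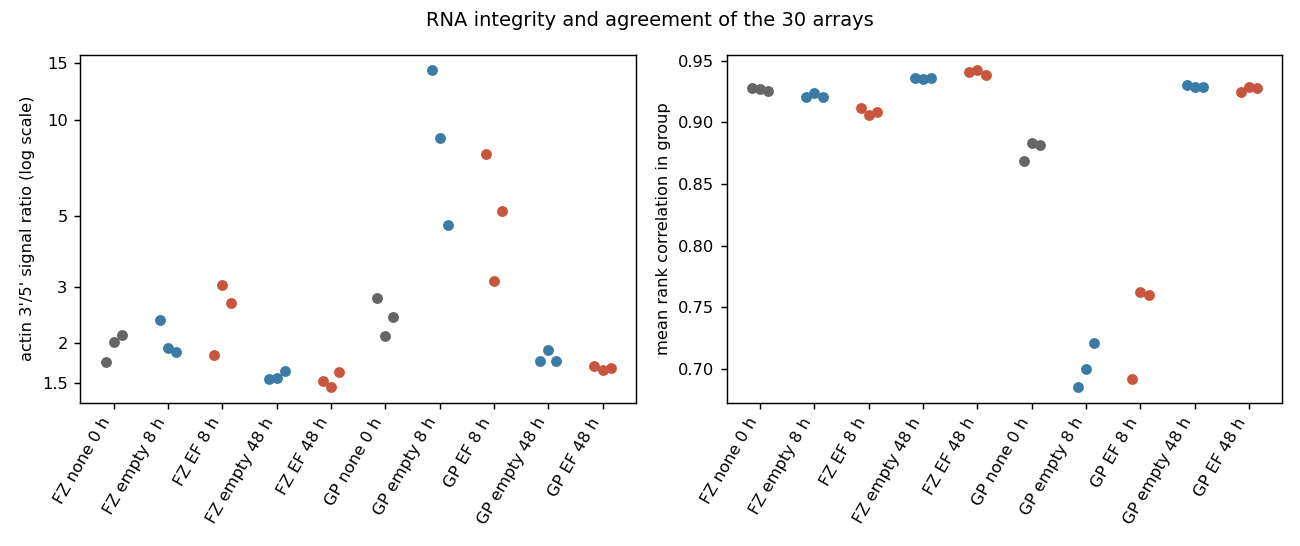
Left, actin 3'/5' signal ratio (log axis) and right, mean rank correlation of each array with the other arrays of its group; each point is 1 array, EF is EWS-FLI1 and none is untransduced. The 6 GP arrays of 8 h span ratios of 3.13 to 14.3 and correlations of 0.686 to 0.763, apart from the other 24.

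Before transduction, FZ cells carried higher levels of genes of the joint surface, tendon and connective tissue, and GP cells carried higher levels of genes of hypertrophic cartilage and bone. Prg4, which encodes the joint lubricant lubricin, was higher in FZ cells by 2.74 ± 0.31 (8.31 ± 0.13 against 5.58 ± 0.09, mean ± SD; adjusted p = 9.3e-07). Tbx4, a hindlimb transcription factor, was higher by 3.49 ± 0.50 (adjusted p = 3.4e-05), the matrix gene Ecm2 by 2.98 ± 0.42 and Barx1, a homeobox gene of joint development, by 2.33 ± 0.42. In the opposite direction, the bone sialoprotein gene Ibsp differed by -7.51 ± 0.77 (2.45 ± 0.35 against 9.96 ± 0.92; adjusted p = 2.1e-07) and the collagenase gene Mmp13 by -6.64 ± 0.46 (adjusted p = 4.9e-10). The neutrophil genes S100a9, S100a8 and Olfm4 differed by -6.18 ± 0.73, -5.73 ± 0.71 and -5.89 ± 0.55. Among chondrocyte genes, the difference was -0.21 for the type II collagen gene Col2a1, -0.02 for the cartilage master regulator Sox9 and -0.08 for the aggrecan gene Acan. None of them was called, although the arrays of the 2 groups did not overlap for Col2a1 and Acan.

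In all, 518 genes were higher and 685 lower in FZ than in GP cells at 0 h, and the values of the 2 groups did not overlap for 36.8% of genes, against 10% by chance. Of 26 articular genes 11 were higher, 1 lower and 14 not called (14 higher and 3 lower adjusted over the list alone; camera adjusted p = 4.96e-06). Of 16 tendon and fibroblast genes 8 were higher and 8 not called (9 higher adjusted over the list alone; adjusted p = 2.95e-07). Dpt, the dermatopontin gene, was higher by 2.25 ± 0.47, Col14a1 by 2.13 ± 0.32 and the tenomodulin gene Tnmd by 1.67 ± 0.32. Of 11 hypertrophic genes 10 were lower (10 adjusted over the list alone; adjusted p = 7.08e-18). Of 13 osteoblast genes 11 were lower (11 adjusted over the list alone; adjusted p = 3.42e-14). Among them were Phex, a mineralization gene, at -5.47 ± 0.70, the alkaline phosphatase gene Alpl at -3.42 ± 0.42 and the parathyroid hormone receptor gene Pth1r at -2.52 ± 0.31. Growth plate cartilage genes as a list were not called, with 1 of 23 higher (1 adjusted over the list alone; adjusted p = 0.52).

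Hedgehog genes were higher in FZ cells at 0 h, with 4 of 11 called (5 adjusted over the list alone; adjusted p = 0.0033). The co-receptor genes Cdon and Boc were higher by 1.63 ± 0.28 and 1.48 ± 0.20. Posterior Hox genes had 3 of 12 higher (7 adjusted over the list alone; adjusted p = 0.00102). Cell cycle genes had 8 of 29 higher (14 adjusted over the list alone; adjusted p = 6.10e-09). Immediate early genes, with 5 of 16 higher (7 adjusted over the list alone; adjusted p = 4.33e-05), included Nr4a1 by 1.20 ± 0.18 and Klf2 by 0.99 ± 0.18. ERK feedback genes had 3 of 12 higher (7 adjusted over the list alone; adjusted p = 0.0018). Known EWS-FLI1-induced targets were higher in FZ cells at 0 h, with 6 higher, 1 lower and 31 not called of 38 (8 and 1 adjusted over the list alone, camera adjusted p = 0.00113). IGF axis genes had 6 of 14 higher (7 higher and 1 lower adjusted over the list alone; adjusted p = 0.000169). This call was lost, with adjusted p = 0.105 with an estimated correlation. Of 17 macrophage and leukocyte genes 9 were lower (12 adjusted over the list alone; adjusted p = 7.60e-11, but adjusted p = 0.107 with an estimated correlation), with Lyz2 at -3.47 ± 0.59. Of 7 osteoclast genes 3 were lower (6 adjusted over the list alone; adjusted p = 1.23e-05, but adjusted p = 0.0844 with an estimated correlation), with Mmp9 at -4.78 ± 0.66. Of 5 erythroid genes 1 was lower (1 adjusted over the list alone; adjusted p = 0.00641, but adjusted p = 0.0795 with an estimated correlation), namely Slc4a1 at -2.91 ± 0.41. The articular, tendon and fibroblast, hypertrophic, osteoblast, Hedgehog, Hox, cell cycle, immediate early, ERK feedback and EWS-FLI1-induced calls held with an estimated correlation. With empty virus, also without the fusion, the EWS-FLI1-induced list was not called at 8 h (14 higher and 6 lower, camera adjusted p = 0.133). Nor was it called with empty virus at 48 h (4 higher and 4 lower, camera adjusted p = 0.929).

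Lists not called at 0 h included TGF-beta and BMP genes, with 6 of 21 higher and 2 lower (7 and 4 adjusted over the list alone; adjusted p = 0.681), and matrix proteases and crosslinking enzymes, with 5 of 21 higher and 5 lower (5 and 8 adjusted over the list alone; adjusted p = 0.347). ETS family and fusion partner genes had 1 of 12 higher and 1 lower (2 and 1 adjusted over the list alone; adjusted p = 0.472), and neural genes had 1 of 19 higher (1 adjusted over the list alone; adjusted p = 0.472). Schwann genes had 0 of 7 called by limma, also over the list alone (adjusted p = 0.595), and keratinocyte genes had 1 of 6 lower (1 adjusted over the list alone; adjusted p = 0.417). The keratinocyte and matrix protease lists were called in 0 of the 17 comparisons. Fli1 and Ewsr1, the mouse genes of the fusion partners, differed by 0.31 and -0.04 and were not called. The count of 1203 genes at 0 h was 704 without FZ replicate 2 or without GP replicate 1 and 734 without FZ replicate 1. It was 3006 with array quality weights, 2755 when only these 6 arrays were fitted, 3613 without the 6 GP arrays of 8 h and 593 with array medians made equal.

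**Figure D2:**
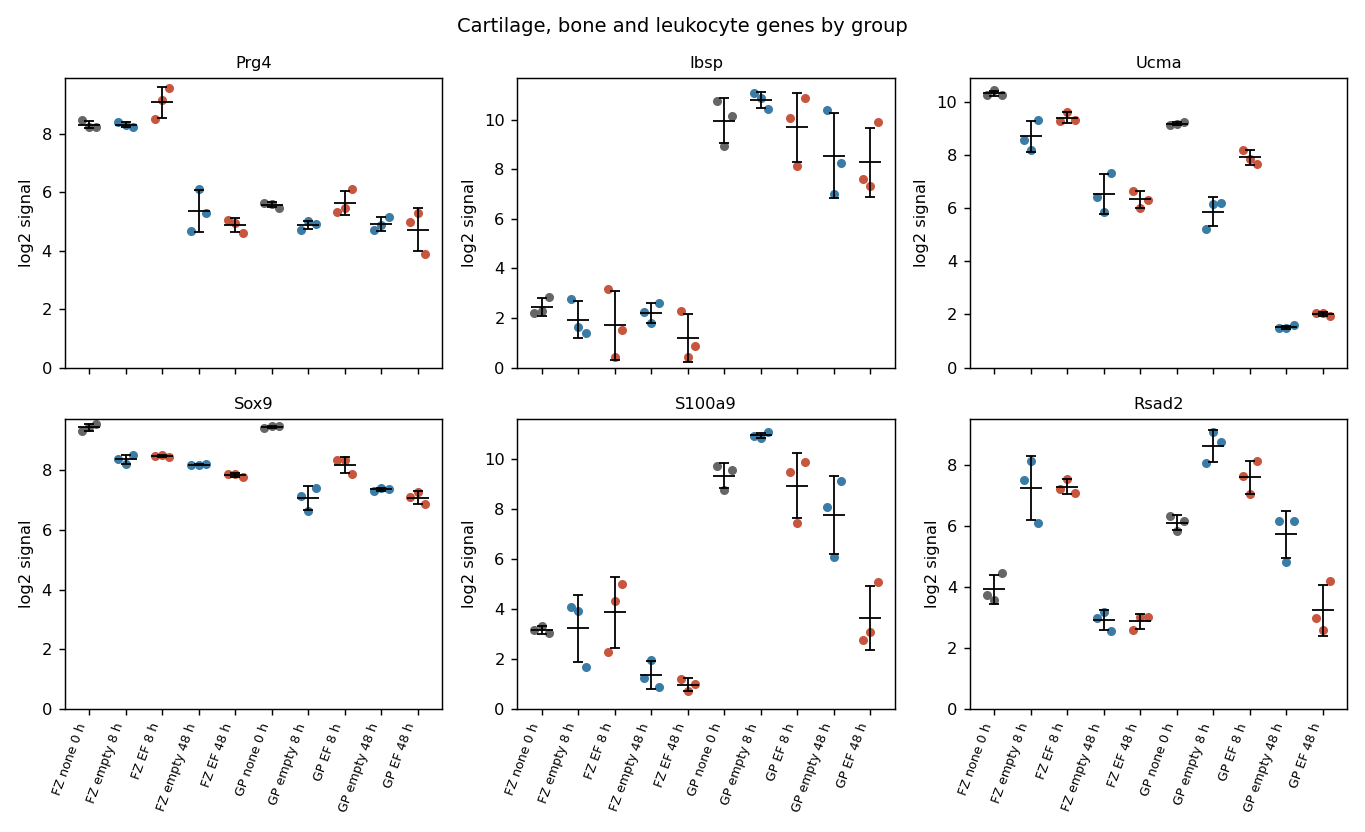
Log2 signals of Prg4, Ibsp, Ucma, Sox9, S100a9 and Rsad2 by group; points are single arrays, bars are mean ± SD, EF is EWS-FLI1 and none is untransduced. Prg4 at 0 h is 8.31 in FZ and 5.58 in GP cells, and Ibsp is 2.45 in FZ and 9.96 in GP cells.

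The comparison of empty virus with 0 h asks what culture and transduction change without the fusion. The source samples differ as well, since all 6 arrays of 0 h were low in Xist and 2 of 3 in each empty-virus group were high. In FZ cells at 48 h, immediate early genes, cholesterol synthesis genes and tendon and fibroblast genes had fallen. The AP-1 gene Fosb changed by -6.47 ± 0.38, Klf2 by -4.72 ± 0.18, the tachykinin gene Tac1 by -6.70 ± 0.30, Mfap4 by -6.60 ± 0.30, Col14a1 by -5.69 ± 0.32 and Prg4 by -2.95 ± 0.31. The annexin gene Anxa3 rose by 4.78 ± 0.13 (adjusted p = 5.8e-20) and the carbonic anhydrase gene Car6 by 5.69 ± 0.35. In GP cells at 48 h, cartilage genes had fallen, with Ucma, a cartilage matrix gene, at -7.65 ± 0.28 (9.17 to 1.52), Scrg1 at -6.66, Ecrg4 at -6.53 ± 0.22 and the chondromodulin gene Cnmd at -4.06 ± 0.17. The smooth muscle gene Tagln rose by 6.14 ± 0.30.

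In FZ cells at 48 h, 2752 genes had risen and 2007 had fallen, and in GP cells 3196 and 2162. All 12 cholesterol synthesis genes fell in both cell types (12 and 12 adjusted over the list alone; camera adjusted p = 1.47e-18 in FZ and 4.59e-20 in GP cells). The sterol sensor gene Insig1 changed by -3.98 ± 0.16 and -4.32 ± 0.16. Of 16 immediate early genes 15 fell in each cell type (adjusted p = 1.27e-25 and 4.59e-20). Of 14 endothelial genes 12 fell in each (adjusted p = 1.29e-06 and 1.13e-05). Of 23 growth plate cartilage genes 18 fell in FZ cells (adjusted p = 2.29e-10, but adjusted p = 0.0868 with an estimated correlation) and 22 in GP cells (adjusted p = 8.55e-28). Of 16 tendon and fibroblast genes 11 fell and 1 rose in FZ cells (adjusted p = 2.34e-08). In GP cells actin cytoskeleton and contractile genes rose, with 10 of 15 up and 1 down (adjusted p = 1.87e-05, but adjusted p = 0.0897 with an estimated correlation). Interferon genes, with 13 of 20 up and 1 down, also rose (adjusted p = 0.00813, but adjusted p = 0.373 with an estimated correlation). Of 5 adipocyte genes 4 rose in GP cells (5 adjusted over the list alone; adjusted p = 0.00203). Of 19 p53 genes 11 rose and 5 fell (adjusted p = 0.0445, but adjusted p = 0.164 with an estimated correlation). Adjusted over the list alone, the counts in this paragraph were the same except for interferon genes, with 14 up and 2 down. The calls for cholesterol synthesis, immediate early and endothelial genes in both cell types, tendon and fibroblast genes in FZ cells and growth plate and adipocyte genes in GP cells held with an estimated correlation. With array medians made equal, the FZ split was 3778 up and 1671 down, and the FZ count of 4759 became 8407 with array quality weights, 8109 when only these 6 arrays were fitted and 7362 without the 6 GP arrays of 8 h.

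At 8 h the same direction was seen in the sterol and immediate early genes. The HMG-CoA synthase gene Hmgcs1 changed by -1.75 ± 0.11 in FZ and -2.23 ± 0.11 in GP cells, and the AP-1 gene Junb by -2.59 ± 0.14 and -2.47 ± 0.14. All 12 cholesterol synthesis genes fell in both (adjusted p = 1.11e-09 and 1.07e-14). Of 16 immediate early genes 12 fell and 1 rose in FZ cells and 14 fell and 1 rose in GP cells (adjusted p = 6.91e-08 and 6.5e-12). Of 11 Hedgehog genes 10 fell in FZ and 9 in GP cells (adjusted p = 5.22e-05 and 0.00137). These 3 lists held with an estimated correlation, and the counts at 8 h were the same adjusted over the list alone. In FZ cells 11 of 15 glycolysis and hypoxia genes fell (adjusted p = 1.67e-05, but adjusted p = 0.0673 with an estimated correlation). The keratin gene Krt18 rose by 4.74 ± 0.35. In GP cells, whose arrays had the high 3'/5' ratios at 8 h, all 23 growth plate genes fell (adjusted p = 9.27e-13, but adjusted p = 0.149 with an estimated correlation), Sox9 among them by -2.40 ± 0.14. The myeloid lectin gene Clec4n and the chemokine gene Ccl5 rose by 5.86 ± 0.66 and 5.28 ± 0.49. At 8 h, 2464 genes had risen and 2603 had fallen in FZ cells, and 2776 and 3212 in GP cells. With array medians made equal the GP split was 1596 up and 3728 down, that scaling moving the median of all genes by -0.12. With array quality weights the FZ count of 5067 became 7859 and the GP count of 5988 became 3176. The GP count was 2885 when only its 6 arrays were fitted.

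FZ and GP cells were also compared within each transduced state. With empty virus at 48 h, cartilage genes were higher in FZ cells, with Ucma at 5.01 ± 0.28 (6.53 against 1.52), Ecrg4 at 4.90 ± 0.22 and Cnmd at 3.44 ± 0.17. S100a8 was lower at -6.66 ± 0.71, Ibsp at -6.33 ± 0.77, Mmp13 at -5.32 ± 0.46 and the fatty acid binding protein gene Fabp4 at -3.53 ± 0.24. Of 23 growth plate genes 19 were higher (20 adjusted over the list alone; adjusted p = 4.07e-41), and of 11 hypertrophic genes 8 were lower (9 adjusted over the list alone; adjusted p = 2.25e-13). Of 17 macrophage genes 15 were lower (17 adjusted over the list alone; adjusted p = 6.4e-21). Of 16 unfolded protein and amino acid stress genes 7 were higher (10 adjusted over the list alone; adjusted p = 5.87e-10). These 4 calls held with an estimated correlation. Interferon genes had 4 of 20 lower (14 lower and 1 higher adjusted over the list alone; adjusted p = 3.75e-06, but adjusted p = 0.232 with an estimated correlation). There were 649 genes higher and 796 lower in FZ cells, and 41.5% of genes did not overlap. The count of 1445 was 952 without the FZ empty-virus replicate 3, 4213 with array quality weights, 3462 when only these 6 arrays were fitted and 3145 without the 6 GP arrays of 8 h. Across all genes the differences at 0 h and with empty virus at 48 h correlated with r = 0.385, genes not being independent replicates, and 881 of the 1203 genes called at 0 h had the same sign.

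With EWS-FLI1 at 48 h, the cartilage difference was again present, with Ucma at 4.30 ± 0.28, Scrg1 at 4.19 ± 0.26 and Cnmd at 2.67 ± 0.17. Single genes lower in FZ cells included Ibsp at -7.08 ± 0.77, Mmp13 at -5.12 ± 0.46 and Fabp4 at -3.55 ± 0.24. Of 23 growth plate genes 16 were higher and 1 lower (18 and 1 adjusted over the list alone; adjusted p = 5.05e-39). Of 26 articular genes 6 were higher and 1 lower (8 and 3 adjusted over the list alone; adjusted p = 7.64e-07). Of 11 hypertrophic genes 6 were lower (10 adjusted over the list alone; adjusted p = 9.3e-21). All 3 calls held with an estimated correlation. Macrophage genes had 2 of 17 lower (3 adjusted over the list alone; adjusted p = 0.00423, but adjusted p = 0.492 with an estimated correlation). There were 238 genes higher and 246 lower, and 30.3% of genes did not overlap. The count of 484 was 298 without FZ EWS-FLI1 replicate 1, 312 without GP EWS-FLI1 replicate 3, 2106 with array quality weights, 1621 when only these 6 arrays were fitted and 1475 without the 6 GP arrays of 8 h.

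At 8 h, when the GP arrays had the high 3'/5' ratios, Prg4 was again higher in FZ cells and Ibsp and S100a9 lower. With empty virus, Prg4 was higher in FZ cells by 3.43 ± 0.31 and Ibsp, S100a9 and the prostaglandin dehydrogenase gene Hpgd differed by -8.84 ± 0.77, -7.73 ± 0.73 and -6.51 ± 0.76. With EWS-FLI1, Tbx4 was higher by 3.67 ± 0.50, Prg4 by 3.44 ± 0.31 and the cartilage matrix gene Cilp by 3.54 ± 0.53. The type X collagen gene Col10a1 differed by -5.97 ± 0.81. Of 11 hypertrophic genes 9 were lower and 1 higher with empty virus (adjusted p = 7.83e-09) and 10 were lower with EWS-FLI1 (adjusted p = 1.0e-13). Of 16 immediate early genes 11 were higher with empty virus (adjusted p = 1.31e-05) and 10 were higher and 1 lower with EWS-FLI1 (adjusted p = 8.2e-05). These calls held with an estimated correlation. Adjusted over the list alone, the counts with empty virus were the same, and with EWS-FLI1 10 hypertrophic genes were lower and 1 higher and 12 immediate early genes higher and 1 lower. Of 17 macrophage genes 14 were lower with empty virus (adjusted p = 6.1e-10, but adjusted p = 0.163 with an estimated correlation) and 8 with EWS-FLI1 (14 and 9 adjusted over the list alone; adjusted p = 4.02e-05, but adjusted p = 0.339 with an estimated correlation). Glycolysis and hypoxia genes with EWS-FLI1 had 2 of 15 higher and 4 lower (3 and 5 adjusted over the list alone). Their median was -0.38, their mean 0.01, and the test called them lower (adjusted p = 0.0332, but adjusted p = 0.311 with an estimated correlation). With empty virus 2807 genes were higher and 2290 lower, and with EWS-FLI1 1560 and 1232. With array medians made equal, which moved the median of all genes by 0.21 in both comparisons, these were 4948 and 1805 with empty virus and 4204 and 982 with EWS-FLI1. The counts of 5097 and 2792 were 2099 and 1238 with array quality weights and 2026 and 537 when only the arrays compared were fitted. They were 1668 and 1477 with a term for the actin ratio.

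At 48 h after transduction of FZ cells, 128 genes were higher and 11 lower with EWS-FLI1 than with empty virus. Inflammatory genes were higher as a list than with empty virus, with 4 of 19 called (camera adjusted p = 2.08e-14). The serglycin gene Srgn was higher by 4.97 ± 0.35 (3.10 ± 0.16 to 8.07 ± 0.17; adjusted p = 7.2e-10), the galectin gene Lgals7 by 4.90 ± 0.53 and the stromelysin gene Mmp3 by 4.68 ± 0.59. The cardiac myosin gene Myh6 was higher by 4.53 ± 0.47, the tetraspanin gene Tspan13 by 4.11 ± 0.19 (adjusted p = 4.6e-14) and the glutamate receptor gene Grik1 by 4.11 ± 0.43. The lower genes included the growth inhibitor Cdkn1c by -0.89 ± 0.13 (adjusted p = 0.00011) and Sertad4 by -0.95 ± 0.18. Cdkn1c was not called with array medians made equal. The groups did not overlap for 25.6% of genes, against 10% by chance.

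Of 38 known EWS-FLI1-induced targets 4 were higher in FZ cells at 48 h and 34 were not called (6 higher adjusted over the list alone; camera adjusted p = 2.73e-05). Among them the uridine phosphorylase gene Upp1 was higher by 3.33 ± 0.53 and the Wnt inhibitor gene Dkk2 by 2.61 ± 0.50 (adjusted p = 0.003). Of 27 EWS-FLI1-repressed targets 1 was higher, the IGF binding protein gene Igfbp3 by 3.03 ± 0.25 (adjusted p = 1.4e-08), and 1 was lower, Cdkn1c (1 and 1 adjusted over the list alone; adjusted p = 0.626). Of 19 inflammatory genes 4 were higher over all genes and 10 adjusted over the list alone. The chemokine genes Cxcl1 and Cxcl2 were higher by 3.16 ± 0.28 and 2.27 ± 0.37, and the NF-kappaB inhibitor gene Nfkbia by 1.15 ± 0.15. Immediate early genes had 1 of 16 higher, Fos by 1.09 ± 0.17, a call lost with array medians made equal (5 higher adjusted over the list alone; adjusted p = 1.47e-05). The p53 genes had 0 of 19 called by limma, also over the list alone, and the list was higher (adjusted p = 0.000307). The EWS-FLI1-induced, inflammatory, immediate early and p53 calls held with an estimated correlation.

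The remaining list calls in FZ cells at 48 h were lost with an estimated correlation. Wnt genes had 3 of 21 higher (3 adjusted over the list alone; adjusted p = 0.0384, but adjusted p = 0.0714 with an estimated correlation). These were Dkk2, Wif1 at 1.49 ± 0.37 and the secreted antagonist gene Sfrp1 at 1.35 ± 0.23. The call of Wif1 was lost without any 1 of the 6 arrays, where its values were 1.41 to 1.63, and with quantile normalization of log2 values, no filter, no trend or the mean of the probe sets. Endothelial genes had 1 of 14 higher (1 adjusted over the list alone; adjusted p = 0.0384, but adjusted p = 0.203 with an estimated correlation), namely Sox17 at 2.95 ± 0.40. Growth plate genes had 0 of 23 called by limma, 6 lower adjusted over the list alone and a median of -0.36 (adjusted p = 2.08e-14, but adjusted p = 0.0755 with an estimated correlation). Sox9 was at -0.35 and Col2a1 at -0.02. Cell cycle genes had 0 of 29 called by limma, also over the list alone, and were higher as a list (adjusted p = 8.03e-09, but adjusted p = 0.0636 with an estimated correlation). Unfolded protein and amino acid stress genes had 0 of 16 called, 2 lower adjusted over the list alone (adjusted p = 0.000847, but adjusted p = 0.166 with an estimated correlation). Interferon and cholesterol genes, with 0 of 20 and 0 of 12 called, also over the list alone, were lower (adjusted p = 0.0169 and 0.0266, but adjusted p = 0.668 and 0.468 with an estimated correlation). Mouse Fli1 and Ewsr1 differed by 0.08 and 0.01, and their probe sets check nothing about a human fusion transcript. The count of 139 genes was 88 without FZ EWS-FLI1 replicate 3. It was 1450 with array quality weights, of which 796 up and 654 down, 720 when only these 6 arrays were fitted and 480 without the 6 GP arrays of 8 h.

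In GP cells at 48 h 92 of the genes higher in FZ cells were also higher with EWS-FLI1, and macrophage and interferon genes were lower, with 12 of 17 and 10 of 20 called (camera adjusted p = 5.0e-26 and 1.02e-24). The desmosomal gene Pkp1 was higher by 4.86 ± 0.72, Myh6 by 4.76 ± 0.47 (adjusted p = 6.1e-07), Lgals7 by 4.33 ± 0.53, Cited1 by 4.10 ± 0.54 and Tspan13 by 4.08 ± 0.19 (adjusted p = 5.5e-14). The neutrophil genes S100a8 and S100a9 changed by -4.31 ± 0.71 and -4.12 ± 0.73, S100a8 going from a mean of 8.35 to 4.04. The interferon-induced Schlafen gene Slfn4 changed by -4.05 ± 0.73 and the myeloid lectin gene Clec4d by -3.32 ± 0.54. In total 180 genes were higher and 165 lower, and 24.7% of genes did not overlap, against 10% by chance.

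Of 17 macrophage and leukocyte genes 12 fell in GP cells at 48 h (16 adjusted over the list alone; camera adjusted p = 5.0e-26), with the cathepsin gene Ctss at -2.60 ± 0.48 (8.39 to 5.79) and the macrophage antigen gene Adgre1 at -1.93 ± 0.37. Of 20 interferon genes 10 fell (16 adjusted over the list alone; adjusted p = 1.02e-24), with the antiviral gene Rsad2 at -2.49 ± 0.44. Both calls held with an estimated correlation. The median log2 signal of the macrophage list in GP cells was 5.62 at 0 h, 6.36 with empty virus and 4.04 with EWS-FLI1 at 48 h. In FZ cells at 48 h it was 3.21 and 3.48. The median of the interferon list was 2.74, 5.10 and 2.49 in GP cells and 2.70, 2.94 and 2.63 in FZ cells. Muscle genes had 4 of 18 lower (12 adjusted over the list alone; adjusted p = 1.9e-14, but adjusted p = 0.067 with an estimated correlation). Actin cytoskeleton and contractile genes had 3 of 15 lower (5 adjusted over the list alone; adjusted p = 1.58e-05, but adjusted p = 0.171 with an estimated correlation). Tendon and fibroblast genes had 1 of 16 higher and 2 lower (1 and 2 adjusted over the list alone; adjusted p = 0.00755, but adjusted p = 0.171 with an estimated correlation). Among them the periostin gene Postn fell by 2.03. Cell cycle genes had 2 of 29 higher (6 adjusted over the list alone; adjusted p = 2.1e-09, but adjusted p = 0.067 with an estimated correlation). The p53 genes had 1 of 19 higher (1 adjusted over the list alone; adjusted p = 0.00755, but adjusted p = 0.104 with an estimated correlation). Adipocyte genes, with 0 of 5 called and 1 lower adjusted over the list alone, were lower (adjusted p = 0.0107, but adjusted p = 0.104 with an estimated correlation). Growth plate genes, with 0 of 23 called, also over the list alone, were higher (adjusted p = 0.0412, but adjusted p = 0.602 with an estimated correlation).

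Known EWS-FLI1-induced targets in GP cells at 48 h were not called as a list, with 5 of 38 higher, 1 lower and 32 not called (6 and 3 adjusted over the list alone; adjusted p = 0.163). Upp1 was higher by 3.64 ± 0.53, while Dkk2 differed by 0.72 and was not called (adjusted p = 0.88). EWS-FLI1-repressed targets had 3 of 27 higher and 2 lower (3 and 3 adjusted over the list alone; adjusted p = 0.928). Igfbp3 was higher by 2.21 ± 0.25 and Cdkn1c differed by -0.81 ± 0.13, the latter not called with array medians made equal. Inflammatory genes had 3 of 19 higher (4 higher and 2 lower adjusted over the list alone; adjusted p = 0.163), with Cxcl1 at 1.80 ± 0.28. IGF axis genes had 3 of 14 higher and 1 lower (4 and 1 adjusted over the list alone; adjusted p = 0.0651). Fli1 and Ewsr1 differed by -0.56 and 0.19. The count of 345 genes was 122 without GP EWS-FLI1 replicate 2, 198 without replicate 1 of that group, and 168 and 176 without GP empty-virus replicates 1 and 3. It was 1488 with array quality weights, 725 when only these 6 arrays were fitted and 1071 without the 6 GP arrays of 8 h.

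**Figure D3:**
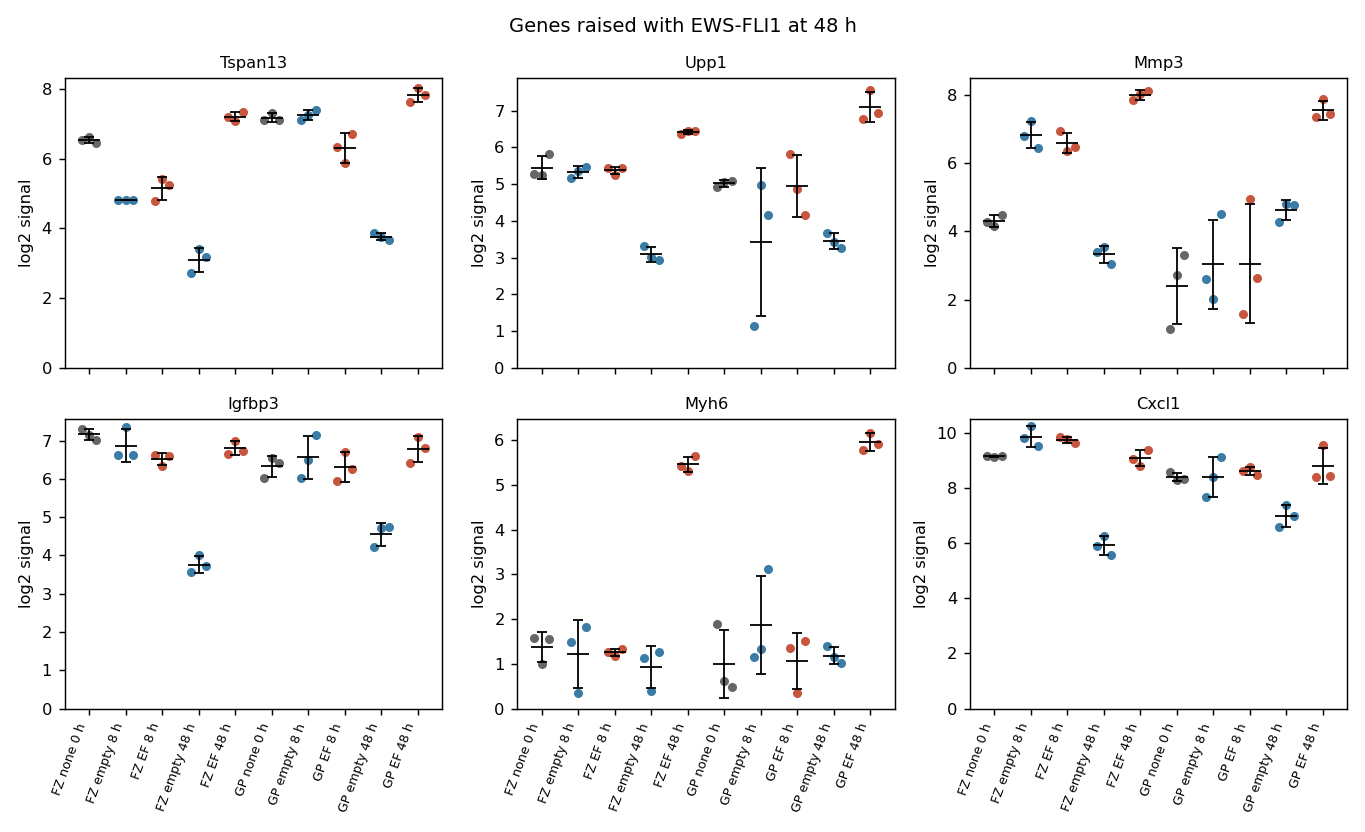
Log2 signals of Tspan13, Upp1, Mmp3, Igfbp3, Myh6 and Cxcl1 by group; points are single arrays, bars are mean ± SD, EF is EWS-FLI1 and none is untransduced. In FZ cells Tspan13 is 6.54 at 0 h, 3.10 with empty virus at 48 h and 7.22 with EWS-FLI1 at 48 h, whereas Myh6 is 1.38, 0.93 and 5.46.

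For several of these genes the EWS-FLI1 level at 48 h lay near the level before transduction, the empty-virus level being lower than both. In FZ cells Igfbp3 was 7.16 at 0 h, 3.76 with empty virus and 6.79 with EWS-FLI1 at 48 h, and Cxcl1 was 9.14, 5.92 and 9.08. In GP cells Igfbp3 was 6.33, 4.56 and 6.77, and Tspan13 was 7.18, 3.76 and 7.84. Myh6 and Lgals7 were at or below 2.08 at 0 h in both cell types and rose above that level with EWS-FLI1, Lgals7 to 6.25 in FZ and 5.04 in GP cells.

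The 48 h effects in FZ and GP cells, which share no arrays, correlated with r = 0.461 across 13985 genes, genes not being independent replicates. Within each virus the arrays high in Xist had the same replicate numbers in FZ and GP cells. Both effects may thus rest on shared source samples, and a difference of samples between the viruses could appear in both. There were 92 genes higher in both, against 1.65 for independent lists, 3 lower in both, against 0.13, and 0 called by limma in opposite directions. The 3 lower genes were Cdkn1c, Gpr137b and Mycn. Mycn turned to 1.27 in FZ and 1.54 in GP cells with the mean of the probe sets, and Cdkn1c was not called with array medians made equal. Gpr137b, at -0.64 in both cell types and chosen in GP cells after its values were seen, was not called with the mean of the probe sets, nor in FZ cells with array medians made equal. Its call was lost without FZ empty-virus replicate 3 (-0.53), FZ EWS-FLI1 replicate 2 (-0.63) or GP EWS-FLI1 replicate 2 (-0.56). Of the 139 genes called in FZ cells 134 had the same sign in GP cells, and of the 345 called in GP cells 303 had the same sign in FZ cells. Upp1, Tspan13, Myh6, Lgals7, Wnt16, Mmp3, Igfbp3 and Cxcl1 were among the genes higher in both, with Wnt16 at 3.28 in FZ and 3.14 in GP cells.

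**Figure D4:**
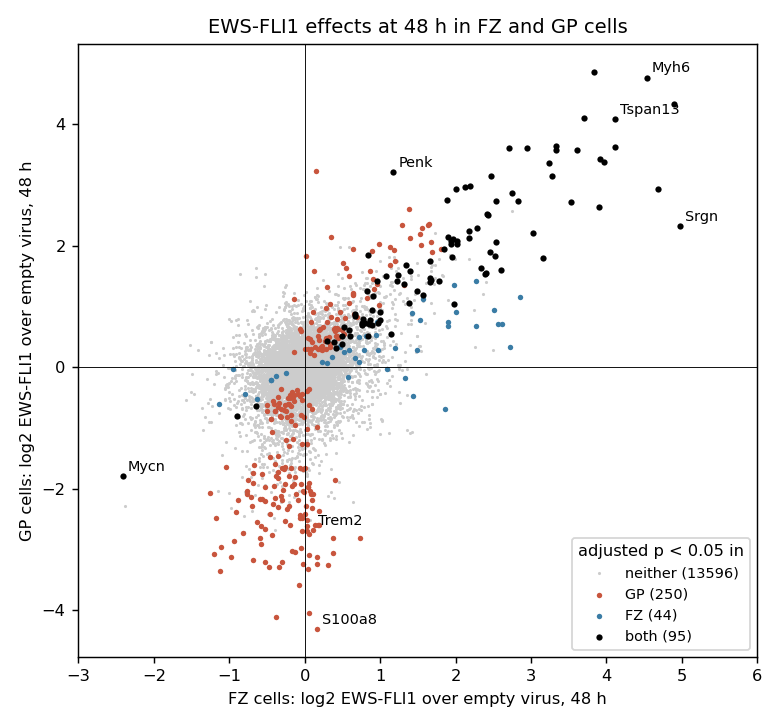
Log2 difference of EWS-FLI1 over empty virus at 48 h in FZ cells (horizontal) and GP cells (vertical); each point is 1 of 13985 genes, coloured by the cell type in which its adjusted p is below 0.05. Of these, 95 genes are called in both, 44 in FZ but not GP cells and 250 in GP but not FZ cells.

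The test of the difference between the 48 h effects, FZ minus GP, called 3 genes by interaction contrast. Penk, the proenkephalin gene, differed by -2.05 ± 0.28 (adjusted p = 0.00096), going from 6.98 to 8.15 in FZ and from 5.07 to 8.28 in GP cells. It was not called with array medians made equal. Trem2, a receptor gene of macrophages and osteoclasts, differed by 2.80 ± 0.46 (adjusted p = 0.0098), with 0.79 and 0.90 in FZ cells and 3.47 and 0.78 in GP cells. FZ cells thus had less Trem2 signal to lose than GP cells. Cryab, a small heat shock protein gene, differed by 2.02 ± 0.33 (adjusted p = 0.0098), with 6.78 and 6.82 in FZ and 7.31 and 5.33 in GP cells. Trem2 was not called without FZ EWS-FLI1 replicate 2, where its value was 2.70, nor with array medians made equal, a smaller offset, no filter or quantile normalization of log2 values. Cryab was not called without FZ empty-virus replicate 3 or FZ EWS-FLI1 replicate 2, where its values were 1.83 and 1.93, nor with the mean of the probe sets. Upp1 and Mmp3 differed by -0.31 and 1.75 and were not called. No list member was called over all genes, and 408 genes had an unadjusted p below 0.05 in limma. Macrophage genes had 11 of 17 higher adjusted over the list alone (camera adjusted p = 6.45e-34) and interferon genes 2 of 20 (adjusted p = 3.07e-19). Both calls held with an estimated correlation.

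Further lists differed between the 48 h effects only with the preset correlation. Growth plate genes had 7 of 23 lower adjusted over the list alone (adjusted p = 1.52e-20, but adjusted p = 0.0548 with an estimated correlation). Inflammatory genes had 5 of 19 higher (adjusted p = 4.31e-09, but adjusted p = 0.0594 with an estimated correlation). Muscle genes were higher with 0 of 18 called (adjusted p = 3.93e-10, but adjusted p = 0.0895 with an estimated correlation). Unfolded protein and amino acid stress genes were lower with 1 of 16 called over the list alone (adjusted p = 1.78e-06, but adjusted p = 0.0592 with an estimated correlation). EWS-FLI1-induced targets were higher with 0 of 38 called over the list alone (adjusted p = 0.0474, but adjusted p = 0.0594 with an estimated correlation). The other 5 lists with a preset call were actin (adjusted p = 0.000598), cholesterol (0.0012), tendon (0.00246), ERK feedback (0.00345) and immediate early genes (0.00485), with 0, 0, 1, 0 and 1 members called over the list alone. They had adjusted p = 0.198, 0.176, 0.105, 0.0594 and 0.105 with an estimated correlation. The count of 3 genes, 2 higher and 1 lower, was 28 without GP EWS-FLI1 replicate 3, 13 without GP empty-virus replicate 2, 5 without FZ empty-virus replicate 2 and 1 without FZ EWS-FLI1 replicate 2. It was 287 with array quality weights, 31 without the 6 GP arrays of 8 h and 17 when only the 4 groups were fitted. Higher and lower genes were 2 and 0 with array medians made equal and 1 and 1 with quantile normalization of log2 values.

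At 8 h in FZ cells, no gene passed the test for EWS-FLI1: limma called 0 genes, with 267 at an unadjusted p below 0.05. For 1402 of 13985 genes the groups did not overlap, against 10% by chance. Upp1, Mmp3, Igfbp3 and Dkk2 differed by 0.04, -0.24, -0.35 and -0.76. Without FZ EWS-FLI1 replicate 1 the count was 4, with 2 up and 2 down. Muscle, inflammatory, ERK feedback and unfolded protein and amino acid stress genes were lower by camera, each with 0 members called by limma, also over the list alone (adjusted p = 0.0011, 0.00279, 0.0364 and 3.52e-05). All of these were lost (adjusted p = 0.809, 0.794, 0.282 and 0.160 with an estimated correlation).

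At 8 h in GP cells, Sox9 and Ucma were higher and Ccl6 and Il6 lower with EWS-FLI1, on the arrays whose mean 3'/5' ratio was 9.23 with empty virus and 5.36 with EWS-FLI1. The fit over all arrays called 1595 genes higher and 1591 lower. Sox9 was higher by 1.13 ± 0.14, Ucma by 2.04 ± 0.28, Trappc5 by 3.12 ± 0.39 and the monooxygenase gene Moxd1 by 3.06 ± 0.42. The chemokine gene Ccl6 differed by -3.93 ± 0.47, the pre-B cell genes Vpreb1 and Igll1 by -4.26 ± 0.70 and -3.89 ± 0.69, Il6 by -3.52 ± 0.69 and mouse Fli1 by -2.15 ± 0.30 (5.97 to 3.82). The groups did not overlap for 2234 of 13985 genes, against 10% by chance. With array quality weights 2 genes were called, and the calls of the genes named here are lost.

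The list tests of the 8 h effect in GP cells were all lost with an estimated correlation. Interferon genes had 2 of 20 lower, with all 20 below 0 (1 lower adjusted over the list alone, camera adjusted p = 0.00587). Muscle genes had 4 of 18 lower and osteoclast genes 2 of 7 (4 and 2 adjusted over the list alone, camera adjusted p = 0.0228 and 0.039). With an estimated correlation each of these 3 lists had camera adjusted p = 0.5505. Growth plate genes had 18 of 23 higher (19 adjusted over the list alone; adjusted p = 4.34e-09, but adjusted p = 0.524 with an estimated correlation). Cholesterol genes had 8 of 12 higher (10 adjusted over the list alone; adjusted p = 9.58e-06, but adjusted p = 0.508 with an estimated correlation). Unfolded protein and amino acid stress genes had 6 of 16 higher and 1 lower, and glycolysis and hypoxia genes 5 of 15 higher (7 and 1, and 6 and 1, adjusted over the list alone; adjusted p = 0.0228 and 0.0347, but adjusted p = 0.524 and 0.526 with an estimated correlation). Macrophage genes had 11 of 17 lower (12 adjusted over the list alone; adjusted p = 1.1e-05, but adjusted p = 0.526 with an estimated correlation). Inflammatory genes had 9 of 19 lower (9 adjusted over the list alone; adjusted p = 0.000108, but adjusted p = 0.524 with an estimated correlation). EWS-FLI1-induced targets had 2 of 38 higher and 5 lower (3 lower adjusted over the list alone; adjusted p = 0.470). EWS-FLI1-repressed targets had 7 of 27 higher and 7 lower (7 and 7 adjusted over the list alone; adjusted p = 0.310). The count of 3186 genes was 57 when only these 6 arrays were fitted and 1728 with array medians made equal.

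The contrast of the 8 h effects between cell types called 464 genes higher and 474 lower in FZ than in GP cells. It subtracts the GP effect, measured on the same GP arrays, so a sign turned from that effect is built in. Ccl6 was at 4.59 ± 0.66, Vpreb1 at 5.30 ± 0.99, Sox9 at -1.01 ± 0.20 and Trappc5 at -3.29 ± 0.56. Macrophage genes had 3 of 17 higher (10 adjusted over the list alone; adjusted p = 3.05e-06, but adjusted p = 0.661 with an estimated correlation). Growth plate genes had 5 of 23 lower (11 adjusted over the list alone; adjusted p = 9.37e-07, but adjusted p = 0.661 with an estimated correlation). Cholesterol genes had 4 of 12 lower (6 adjusted over the list alone; adjusted p = 8.75e-05, but adjusted p = 0.464 with an estimated correlation). These 4 genes were not called with array quality weights or when only the 4 groups were fitted. The count of 938 was 1 with array quality weights or with only these 4 groups, and 102 with array medians made equal. It was 2329 without GP empty-virus replicate 3, 1849 without GP EWS-FLI1 replicate 3, and 380 and 595 without FZ empty-virus replicates 3 and 1. It was 454 and 476 without FZ EWS-FLI1 replicates 2 and 3, and 1910 without the 3 GP arrays of 8 h with the highest actin ratio.

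The change of the EWS-FLI1 effect from 8 h to 48 h was tested in each cell type. In FZ cells 68 genes were higher and 3 lower, with Lgals7 at 5.41 ± 0.74, Srgn at 5.23 ± 0.50 (adjusted p = 5.3e-07), Mmp3 at 4.92 ± 0.84 and Cxcl1 at 3.29 ± 0.40. EWS-FLI1-induced targets had 3 of 38 higher (6 adjusted over the list alone; camera adjusted p = 1.58e-06), inflammatory genes 3 of 19 higher (6 adjusted over the list alone; adjusted p = 1.6e-16). Immediate early genes had 0 of 16 called by limma, with 1 higher adjusted over the list alone (adjusted p = 4.36e-05). These 3 calls held with an estimated correlation. Growth plate genes had 0 of 23 called, 1 lower adjusted over the list alone (adjusted p = 3.34e-12, but adjusted p = 0.105 with an estimated correlation). The count of 71 was 40 without FZ empty-virus replicate 3 or FZ EWS-FLI1 replicate 3 of 48 h, 45 without FZ empty-virus replicate 1 of 48 h. It was 46 and 44 without FZ empty-virus replicates 1 and 2 of 8 h and 43 without FZ EWS-FLI1 replicate 3 of 8 h. It was 494 with array quality weights, 190 with only the 4 groups and 210 without the 6 GP arrays of 8 h.

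In GP cells 499 genes had a higher and 481 a lower EWS-FLI1 effect at 48 h than at 8 h, with Lgals7 at 6.09 ± 0.74, Myh6 at 5.56 ± 0.67, Pcdh17 at 5.43 ± 0.53 and Sox9 at -1.40 ± 0.20, the last not called when only the 4 groups were fitted. The 8 h side rests on the arrays with high 3'/5' ratios. Cell cycle genes had 8 of 29 higher (11 higher and 1 lower adjusted over the list alone; adjusted p = 6.05e-06, but adjusted p = 0.319 with an estimated correlation). Inflammatory genes had 8 of 19 higher (9 and 1 adjusted over the list alone; adjusted p = 8.5e-06, but adjusted p = 0.319 with an estimated correlation). Growth plate genes had 4 of 23 lower (8 adjusted over the list alone; adjusted p = 1.6e-05, but adjusted p = 0.535 with an estimated correlation). Cholesterol genes had 4 of 12 lower (7 adjusted over the list alone; adjusted p = 0.000245, but adjusted p = 0.319 with an estimated correlation). The count of 980 was 69 with array quality weights, 21 with only the 4 groups, and 287 with array medians made equal, which moved the median of all genes by -0.11. It was 2096 without the 3 GP arrays of 8 h with the highest ratio. It was 2166 and 1569 without replicate 3 of the GP empty-virus and EWS-FLI1 groups of 8 h. Without 48 h arrays it was 618, 597 and 624 without GP empty-virus replicates 1, 2 and 3 and 650, 558 and 606 without GP EWS-FLI1 replicates 1, 2 and 3.

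Probe sets of Mycn, a proto-oncogene, differed from each other. The probe set that represented the gene, because of its high mean, was 1.67 in FZ and 1.58 in GP cells at 0 h, 11.28 and 11.49 with empty virus at 8 h and 11.27 and 11.38 with empty virus at 48 h. With EWS-FLI1 at 48 h it was 8.86 and 9.59. Another Mycn probe set was 1.49 and 1.52 with empty virus and 6.22 and 6.21 with EWS-FLI1 at 48 h, a rise of 4.72 ± 0.44 in FZ and 4.69 ± 0.44 in GP cells (adjusted p = 1.26e-07 and 1.82e-07). The difference between the cell types was 0.03. At 0 h this probe set was 4.945 in FZ and 4.285 in GP cells, so its level with empty virus at 48 h lay below that before transduction. The remaining Mycn probe set differed by 1.49 ± 0.53 in FZ and 1.74 ± 0.53 in GP cells at 48 h and was not called (limma adjusted p = 0.52 and 0.14). A decrease of Mycn with EWS-FLI1 at 48 h by -2.41 ± 0.36 in FZ and -1.79 ± 0.36 in GP cells depended on the probe set taken. It turned to 1.27 and 1.54 with the mean of the probe sets. This gene was the only 1 whose probe sets disagreed in the calls of these 2 comparisons, and the GP value was chosen after its values were seen.

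**Figure D5:**
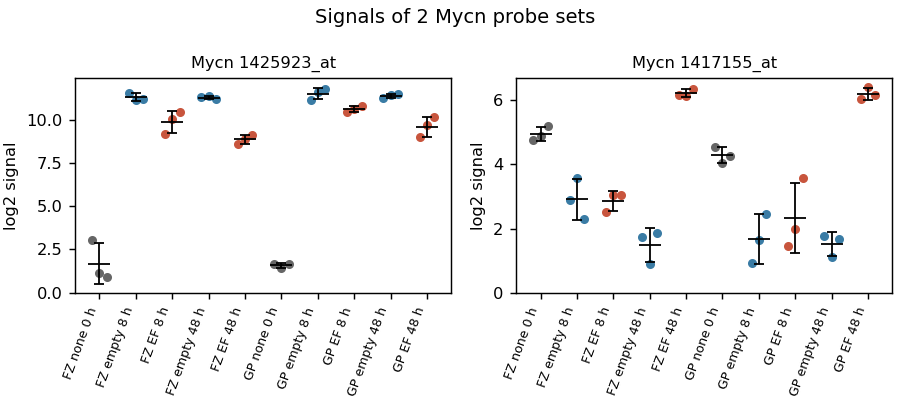
Log2 signals of the Mycn probe set that represents the gene (left) and of another Mycn probe set (right) by group; points are single arrays, bars are mean ± SD, EF is EWS-FLI1 and none is untransduced. The left probe set is 8.61 or higher on all 24 transduced arrays and 3.02 or lower at 0 h.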

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

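Of the tests reported in this part, the relation of the GP effect at 8 h to the slope on the actin ratio and the splits of the samples were written before their results were seen, and the other tests of explanations were chosen after the results were seen.

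The interaction test of the EWS-FLI1 effect at 48 h between FZ and GP cells called Penk (-2.05), Trem2 (2.80) and Cryab (2.02, all log2, FZ minus GP, limma). Each of the 3 calls was lost in at least 1 alternative, the count was 1 to 28 with 1 array left out, and chance was not excluded, with as many genes in 17 of 100 splits. With an estimated correlation the macrophage and leukocyte list (adjusted p = 0.0310) and the interferon list (adjusted p = 0.0472) also differed between the cell types at 48 h. At 8 h the interaction called 938 genes, but 1 with array quality weights or only the 4 groups, and chance was not excluded (7 of 100 splits). The test between 48 h and 8 h called 71 genes in FZ cells, 40 to 63 with 1 array left out. In GP cells it called 980, but 69 with array quality weights and 21 with only the 4 groups, and chance was not excluded (5 of 100 splits). All these splits regroup EWS-FLI1 and empty-virus arrays and so ask about any effect. They cannot decide on chance for a difference of effects. In FZ cells the lists of EWS-FLI1-induced targets (adjusted p = 0.000194), inflammatory genes (adjusted p = 0.0167) and immediate early genes (adjusted p = 0.0391) differed between the times, all with an estimated correlation.

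The macrophage and interferon genes that were lower with EWS-FLI1 in GP cells at 48 h, 2 lists that share 0 members with the other lists, form a pattern open to a difference in cell composition. The different deposited scaling of the EWS-FLI1 and empty-virus arrays of 48 h applies to both cell types. The difference between the cell types had camera adjusted p = 0.0310 for macrophage and 0.0472 for interferon genes with an estimated correlation. With empty virus at 48 h, however, the list medians were 3.21 and 2.94 in FZ against 6.36 and 5.10 in GP cells. FZ cells thus had less signal to lose, and this test cannot decide on scaling. A factor and a power, as inferred here, are removed by quantile normalization. Fewer leukocytes in the GP cultures with EWS-FLI1 may account for the macrophage part and stays open: 16 of 17 markers fitted below 0, the exception being Coro1a (4.57 to 4.90), and the abundant transcripts Lyz2 (9.24 to 6.14), Lyz1 (9.79 to 6.66) and Ctss (8.39 to 5.79) were all lower, values that restate the pattern and do not tell composition from expression. Whether leukocytes also account for the interferon part was not decided: at 0 h, where 16 of 17 macrophage markers were lower in FZ than in GP cells, 11 of 20 interferon genes were (medians 2.70 and 2.74), but with empty virus at 48 h 17 of 20 were (2.94 and 5.10). An effect of EWS-FLI1 on gene expression within the GP cells was not tested apart from composition. On the GP arrays of 8 h, which had high 3'/5' ratios, 16 of 17 macrophage markers and 20 of 20 interferon genes also lay below 0. Neither list call of 8 h held with an estimated correlation. Arrays high in Xist were 2 of 3 in each empty-virus group and 1 of 3 in each EWS-FLI1 group. A difference of source samples between the viruses was therefore not told apart from an effect of EWS-FLI1.

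The 3186 genes called for EWS-FLI1 in GP cells at 8 h come from the 6 arrays with the highest actin 3'/5' ratios. A spread of these arrays larger than the spread pooled over all groups may account for most of the calls, since 2 genes were called with array quality weights. Uneven RNA quality within the groups was not decided: the effect correlated with the slope on the actin ratio by r = -0.0794 across genes, genes not being independent replicates, and 12 of 36 arrangements gave a value as low. An EWS-FLI1 effect shared with 48 h stays open, with r = 0.190 between the GP effects at 8 h and 48 h and 0.155 as the highest of the other splits. Within each virus the arrays high in Xist had the same numbers at both times. A difference of source samples between the viruses could thus also give such an r, and this test cannot tell the 2 apart. The sharing was uneven: of 165 genes called lower at 48 h 140 lay below 0 at 8 h, but of 180 called higher only 105 lay above 0. Among genes called by limma at both times 38 were higher at both, 74 lower at both and 36 opposite.

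The Mycn probe set that represents the gene had a signal on all 24 transduced arrays above every 0 h array, and its lowest empty-virus array lay 8.09 log2 units above the highest 0 h array, whereas the next gene by this gap, Hmga2, reached 2.93. A rise of the Mycn transcript after transduction is argued against as the whole source, because the largest rise of another Mycn probe set in an empty-virus group was -0.39. Vector sequence bound by the probe set is a candidate explanation that stays open and untested, since the count of 24 arrays only restates the pattern. The vector sequence was not used here, so a match was not looked for, and no biological explanation other than the transcript rise was tested.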

How the results depend on the processing

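The fits with the actin or Xist term, with a block of the replicate number within each virus, with recovered MAS5 signals and without GP arrays of 8 h were chosen after the data were seen. All other alternatives were set before. Of 306 results of genes chosen for naming 270 were called, and 163 of these were called under all alternatives run. Of 7593 alternative values of genes 7097 kept direction and side of the threshold, 463 lost the call, 27 gained it and 6 reversed. The reversed values were Dcx in FZ against GP at 0 h, at -1.06 with equal array medians and -0.90 without a filter, where another probe set was taken, Mycn for EWS-FLI1 at 48 h, at 1.27 in FZ and 1.54 in GP cells with the mean of the probe sets, Erg for EWS-FLI1 in GP cells at 8 h, at -1.20 without 3 GP arrays, and Trem2 for EWS-FLI1 in GP cells at 48 h, at 0.28 without a filter, where another probe set was taken. Of 561 list results 144 lost their call with an estimated correlation, 4 with quantile normalization of log2 values and 1 without a filter, and 0 reversed.

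The counts of called genes kept within 1.5 times for the replicate block, the Xist term, recovered MAS5 signals, a smaller offset, quantile normalization of log2 values, no trend, the mean of probe sets and other filters. Recovered signals keep the order of values within each array, on which quantile normalization rests. Their counts could therefore hardly move and do not test the recovery. With array quality weights, counts became 3006 for FZ against GP at 0 h, 1450 and 1488 for EWS-FLI1 at 48 h in FZ and GP cells, 2 for EWS-FLI1 in GP cells at 8 h, 1 and 287 for the difference of effects between cell types at 8 h and 48 h, 494 and 69 for the change of the effect with time in FZ and GP cells, 2099 and 4213 for FZ against GP with empty virus at 8 h and 48 h, 1238 and 2106 with EWS-FLI1, 7859 and 8407 for empty virus against 0 h in FZ cells at 8 h and 48 h and 3176 in GP cells at 8 h. In the same order, with only the groups compared they were 2755, 720 and 725, 57, 1 and 17, 190 and 21, 2026 and 3462, 537 and 1621, then 8109 for FZ cells at 48 h and 2885 for GP cells at 8 h. In fits of other groups alone, the GP arrays of 8 h no longer add to the pooled spread.

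Without the 6 GP arrays of 8 h the counts were 3613 for FZ against GP at 0 h, 480 and 1071 for EWS-FLI1 in FZ and GP cells at 48 h, 31 for the difference at 48 h, 210 for the change with time in FZ cells, 3145 and 1475 for FZ against GP at 48 h with empty virus and EWS-FLI1, and 7362 for empty virus at 48 h in FZ cells. Without 3 of them, the difference at 8 h had 1910 and the change with time in GP cells 2096. With the actin term, FZ against GP at 8 h had 1668 with empty virus and 1477 with EWS-FLI1. With equal array medians, counts were 593 for FZ against GP at 0 h, 1728 for EWS-FLI1 in GP cells at 8 h, 102 for the difference at 8 h, 287 for the change with time in GP cells and 5186 for FZ against GP with EWS-FLI1 at 8 h. The difference at 48 h had 5 genes with an offset 4 times as large and 6 with a floor. The cause of these moves under other scalings was not tested.

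Over all kept probe sets, where more features are tested, calls were 5938 for EWS-FLI1 in GP cells at 8 h, 1464 for the difference at 8 h, 1597 for the change with time in GP cells, 10094 and 5176 for FZ against GP at 8 h with empty virus and EWS-FLI1, 8674 and 8104 for empty virus in FZ cells at 8 h and 48 h, and 11188 and 9176 in GP cells. With a 2-fold minimum they were 528 for FZ against GP at 0 h, 89 and 226 for EWS-FLI1 at 48 h in FZ and GP cells, 1812 in GP cells at 8 h, 2899 and 644 for FZ against GP with empty virus at 8 h and 48 h, 1349 and 239 with EWS-FLI1, 2786 and 2539 for empty virus in FZ cells at 8 h and 48 h, and 3687 and 3082 in GP cells.

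With each array left out in turn, lowest and highest counts were 704 and 1032 for FZ against GP at 0 h, 0 and 4 for EWS-FLI1 in FZ cells at 8 h (limma, 267 at an unadjusted p below 0.05 with all arrays), 88 and 117 at 48 h, 2908 and 4394 in GP cells at 8 h, 122 and 324 at 48 h, 380 and 2329 for the difference at 8 h, 1 and 28 at 48 h, 40 and 63 for the change with time in FZ and 558 and 2166 in GP cells. They were 4055 and 6133 for FZ against GP with empty virus at 8 h, 952 and 1196 at 48 h, 1918 and 4120 with EWS-FLI1 at 8 h, 298 and 411 at 48 h, 4328 and 4387 for empty virus in FZ cells at 8 h, 4018 and 4125 at 48 h, and in GP cells 5155 and 6650 at 8 h and 4571 and 4794 at 48 h. Each array whose omission moved a count by over 1.5 times is named with that comparison above.

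The labels do not say that the replicate number pairs the samples. Of 39 correlations of same-numbered arrays 7 were above 0.1, with a range of -0.32 to 0.36, and in 3 of 13 pairs of groups every array correlated best with its own number. The 12 correlations between 8 h and 48 h were 0.01 to 0.36, 4 of them above 0.1, and the arrays high in Xist had the same numbers in all 4 groups of each virus. The numbers may therefore mark shared samples within each virus, which the contrasts and splits leave out. With the replicate block 1146 genes were called for FZ against GP at 0 h, 133 and 308 for EWS-FLI1 at 48 h in FZ and GP cells and 3 for their difference, and 4 list calls were gained. With the replicate block within each virus they were 1065, 129, 275 and 4, EWS-FLI1 in FZ cells at 8 h had 1 gene in place of 0, all other counts stayed within 1.5 times, and 5 list calls were gained and 5 lost. Signal over background limits dim genes: 27 list members were too dim to be tested.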

Other observations

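Several genes that the report does not describe, or describes in 1 cell type, were higher with EWS-FLI1 than with empty virus at 48 h in both. They were chosen after their values were seen. Among developmental transcription factor genes these were Sox17 (2.95 in FZ and 3.62 in GP cells, log2), Pou3f1 (2.75 and 2.87), Nkx6-1 (2.47 and 3.15), Tbx3 (2.54 and 2.06) and Gata6 (1.93 and 2.04). The protocadherin gene Pcdh17 was higher by 3.34 and 3.57. No theme was tested for them.

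The splits of the samples reported here were set before their results were seen. For comparisons of 3 arrays with 3, 10 splits are too few for a share under 0.05. The real count and the highest of the other splits were 1203 and 1 for FZ against GP at 0 h, 139 and 0 for EWS-FLI1 in FZ cells at 48 h, 345 and 1 in GP cells at 48 h, 0 and 8 in FZ cells at 8 h, with 10 of 10 splits calling as many (limma, 267 genes at an unadjusted p below 0.05 in the real split), and 3186 and 2965 in GP cells at 8 h. For FZ against GP they were 5097 and 274 with empty virus at 8 h, 1445 and 0 at 48 h, 2792 and 232 with EWS-FLI1 at 8 h and 484 and 0 at 48 h. For empty virus against 0 h they were 5067 and 0 in FZ cells at 8 h, 4759 and 0 at 48 h, 5988 and 986 in GP cells at 8 h and 5358 and 0 at 48 h. Of these comparisons, all but that in FZ cells at 8 h had 1 split as large, the real split.

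For the differences of effects, 100 splits were used. They regrouped EWS-FLI1 and empty-virus arrays within each time or each cell type, so they ask about any effect, not a difference of effects. For the change with time in FZ cells 2 of 100 splits, the real one included, gave as many genes as the real 71. The highest other split gave 79. By the rule set before, this count went against chance. Because the splits ask about any effect, they cannot decide on chance for this difference of effects. Chance was not excluded for the change with time in GP cells (5 splits, real count 980, highest other 1757). Nor was it excluded for the difference between cell types at 8 h (7 splits, 938 and 1472) or at 48 h (17 splits, 3 and 57). The split with 57 genes, several times the real 3, may regroup 1 cell type more than the other. Such splits do not measure chance under equal effects, and the count of 57 was not explained.

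Xist, a transcript of the inactive X chromosome, was 9.74 to 10.3 on 12 arrays and 0.40 to 2.99 on the other 18, and the Y-linked Eif2s3y was 0.29 to 1.77 on the former and 5.45 to 6.91 on the latter. All 6 arrays of 0 h were low in Xist, 2 of 3 arrays were high in each empty-virus group and 1 of 3 in each EWS-FLI1 group. Comparisons between these kinds of group are thus unbalanced in Xist. The high arrays were replicates 1 and 2 in all 4 empty-virus groups and replicate 1 in all 4 EWS-FLI1 groups. Of 729 ways to renumber the arrays within these groups, a share of 0.00137 gives such a match.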
